A study of Mus musculus with 18 samples.

How the data were processed

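ChIP-seq was made for YY1 and H3K27me3 in pro-B, pre-B, follicular B and germinal center B cells and for H3K4me1 in pro-B cells, each with an input library, 18 samples in all. The mice were C57BL/6, male and female pooled, and 6 to 14 weeks old, per the labels. For follicular B cells the labels' protocol gives spleens of 5 to 8 weeks, which differs from that range. Per the labels' protocols, libraries were amplified with 18 PCR cycles and sequenced as single-end reads of 100 bases. Processed lists of the 9 ChIP libraries were used. The 9 inputs entered only through the authors' calling of peaks and were not analysed here. Each group was 1 sample, taken from the sample labels.

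Reads were processed with Bowtie 0.12.9, MACS 1.4.2 and HOMER 4.7 on mm9, per the submitters' processing notes. Each YY1 file is a list of peaks called against an input library, per the file headers. These headers call the pro-B, pre-B and follicular lists confident peaks and the germinal center list enriched regions, and they name a pool for the follicular list. The deposited score of a YY1 peak was read as 10 times the negative log10 of its p-value, as MACS writes it. This scale is inferred from the values, and 3100 appears to be the value for a p-value too small to store. The lowest deposited score was 55.97 in pro-B, 81.06 in pre-B, 50.01 in follicular B and 50 in germinal center B cells. Scores were used only to describe and rank peaks within a list, except in the alternative with a common lowest score. The histone regions were called in HOMER's histone style from windows of 500 bp joined into regions, per the file headers. These required a 4-fold ratio over input, a p-value over input of 0.0001 and a Poisson p-value of 0.001, per the file headers. The signal of a region is its tag count scaled to a fixed library size, with at most 1 tag counted per position, per the file headers. The deposited region score was used to rank regions. Region sizes and other positions were used as deposited, with BED starts raised by 1 where printed.

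The total tags of the H3K27me3 libraries ran from 3325200 to 20247632 and the share of tags in regions from 1.04 to 23.32%, per the file headers. The tag threshold for a region was 6 in pro-B, 11 in pre-B, 14 in follicular B and 12 in germinal center B cells, so that the lists have different floors. Numbers of regions and covered lengths were therefore set side by side with no test.

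Overlaps used chromosomes 1 to 19 and X. YY1 peaks overlapping by at least 1 bp counted as shared. A YY1 peak was counted in H3K27me3 where its centre was in a region, and in H3K4me1 where it overlapped a region by at least 1 bp. For the stage patterns the 4 YY1 lists were merged into a union, and a union region counted for each stage with a peak in it. H3K27me3 lists were compared by shared bases over the smaller covered length. Each observed share was set against 1000 circular shifts of the first list within each chromosome, between the lowest start and highest end of any list, with a fixed seed. A share was called different where it fell outside the 2.5 to 97.5 percentiles of the shifts. These are descriptions of the lists with no p-value, because each group had 1 library. Shares carry 95% Wilson intervals, and differences of median scores carry 95% intervals from 1000 bootstrap draws over peaks. Both cover counting error only, since PCR reads without molecular identifiers are not independent and neighbouring peaks are not either.

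Alternatives fixed before the data were examined were the higher-scoring part of each list, equal list length, other overlap rules, peaks reduced to 200 bp, merging, equal covered length and random placement. Moves of each peak by 10 to 100 kb, the common lowest score, equal YY1 list length against H3K27me3, chromosomes 1 to 19 alone and the centre rule for H3K4me1 were added after the data had been seen. The classes of peaks in the comparisons of YY1 with the histone marks, the flanking counts and the distance profiles were also chosen then.

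Regions were named by a rule fixed before the data were examined. It took the 5 highest-scoring YY1 peaks of each stage and the 10 regions shared by all 4 stages with the lowest sum of ranks. It also took the 5 highest-scoring peaks of each stage alone, the 5 widest domains of each histone list after merging within 5 kb, and the 5 widest H3K27me3 domains of 1 stage with no region in another. The text prints part of these. The germinal center domain on chromosome 2 with H3K4me1 in pro-B cells is in that list and was singled out after its values were seen. The gene table at hand is of assembly GRCm38.p6. The files hold positions beyond its last gene on some chromosomes, with 847 regions on chromosome 7 alone, and the notes name mm9. Promoter shares and the gene lists prepared beforehand were therefore not used here.

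The interval code was tested on simulated lists of 5000 peaks. For the overlap of YY1 lists, planted shares of 5.3, 40.58 and 79.78% were found as 5.5, 40.74 and 79.82%. For YY1 in H3K27me3, 100 pairs of unrelated lists gave a mean of 1.03-fold, and 7 fell outside the 95% range. Both lists of a pair were placed at random without clustering, and each pair was set against 200 shifts. How the range behaves for clustered lists was not tested. The interval operations matched a base-by-base count in all of 200 simulated pairs. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.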

Results

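Binding of the zinc finger transcription factor YY1 and the histone marks H3K27me3 and H3K4me1 were mapped by ChIP-seq in mouse B-lineage cells. H3K27me3 is deposited by Polycomb group proteins at silenced genes, and H3K4me1 marks enhancers and the flanks of promoters. Pro-B cells came from the bone marrow of RAG1-/- mice, whose B-lineage development stops before antigen receptor rearrangement. Pre-B cells came from RAG-deficient mice carrying a rearranged IgM transgene. Follicular B cells, the main resting B cells of the spleen, were sorted by their surface markers (CD19+AA4-CD21loCD23hi). For the germinal center stage, CD19+Fas+GL7+ cells were taken from the spleen 8 days after immunization. YY1 and H3K27me3 were each mapped at all 4 stages and H3K4me1 in pro-B cells, with 1 library per mark and stage. None of the comparisons between stages therefore has a replicate check, and all intervals cover counting error only. Genotype, tissue and immunization differed along with stage, so their effects cannot be told apart from those of stage. The H3K27me3 libraries held 3325200 tags in pro-B, 12324639 in pre-B, 20247632 in follicular B and 16405839 in germinal center B cells, and the H3K4me1 library held 24911793. The depth of the YY1 libraries is not given in the sources used here. No gene annotation of mm9, the build of the files, was used here, so regions are given by position and without genes.

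The first comparison asked where YY1 bound at each stage and how far its sites were shared. The YY1 list held 8666 peaks in pro-B, 7506 in pre-B, 5055 in follicular B and 2049 in germinal center B cells. Most of each shorter list lay within the longer ones. Of the germinal center peaks, 85.5% (95% Wilson interval 83.9 to 87.0%) overlapped a pro-B peak, 86.4% (84.9 to 87.8%) a pre-B peak and 85.8% (84.3 to 87.3%) a follicular peak. Follicular peaks overlapped pro-B peaks in 75.2% (73.9 to 76.3%) and pre-B peaks in 76.9% (75.7 to 78.1%) of cases, and 70.1% (69.1 to 71.1%) of the pre-B peaks overlapped a pro-B peak. Across the 6 pairs the overlap was 126 to 290 times the mean of 1000 circular shifts, and 40.9 to 86.0 times the mean of moves of each peak by 10 to 100 kb, outside the range of both. The germinal center list was of another kind than the other 3, as its track line calls it enriched regions and theirs confident peaks, and with 1 common lowest score of 81.06 the lists held 5452, 7506, 3053 and 1254 peaks.

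Merging the 4 lists gave 11859 regions, of which 6112 were found in 1 stage, 2255 in 2, 1815 in 3 and 1677 in all 4 stages. The highest number shared by all 4 lists in the shifts was 1. A further 1750 regions were found in pro-B, pre-B and follicular B cells and missing from the germinal center list. Regions shared by all 4 stages held the higher-scoring peaks of every list. In pro-B cells their median score was 600 against 69.4 for peaks of that stage alone, a difference of 531 (95% bootstrap interval 499 to 551). The corresponding medians were 944 and 109 in pre-B, 351 and 57.9 in follicular B and 127 and 54.6 in germinal center B cells.

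**Figure D1:**
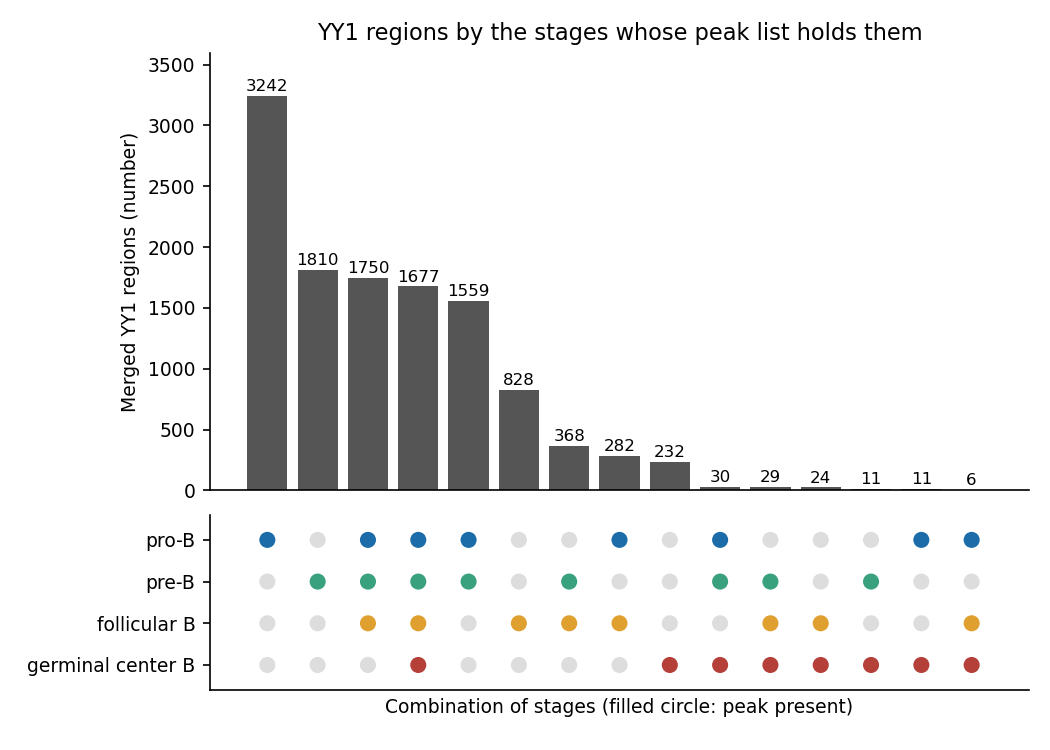
Number of merged YY1 regions (bars, vertical axis) for each combination of stages, with filled circles under a bar marking the stages whose list holds a peak there. Regions of pro-B alone were the most numerous, at 3242, and 1677 regions were found in all 4 stages.

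By the sum of score ranks over the stages, the first 3 shared regions lay on chromosome 8 at 124113626 to 124114886, chromosome 2 at 31525523 to 31526880 and chromosome 3 at 32635124 to 32636676 (mm9). At all 3 the pro-B and pre-B scores were 3100, a value that 53 peaks of the pro-B list and 132 of the pre-B list reached or passed. That value seems to stand for p-values too small to store, so the order of peaks at or above it, and of these regions among the shared ones, cannot be read from the scores. The germinal center scores were 1680 at the region on chromosome 8, 1433 at that on chromosome 2 and 2900 at that on chromosome 3, the last being the highest score of the germinal center list. Each of the first 10 shared regions by this rule overlapped an H3K4me1 region of pro-B cells, and none overlapped an H3K27me3 region of any stage.

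Peaks found in 1 stage alone made up 37.4% of the pro-B list, 24.1% of the pre-B, 16.4% of the follicular and 11.3% of the germinal center list. This order followed the lengths of the lists. With every list limited to its 2047 highest-scoring peaks on chromosomes 1 to 19 and X, the shares were 10.3%, 8.94%, 9.38% and 18.95%. With the common lowest score they were 20.9%, 37.5%, 5.24% and 0.478%, so the order of the stages depended on the setting. Among peaks of pro-B alone, the highest-scoring was on chromosome 6 at 69990223 to 69991390. Its score of 2015 ranked 132 in the pro-B list, and no other list had a peak there. The next pro-B peak of this kind, also on chromosome 6 at 68833287 to 68834537, had a score of 381 and rank 1365. Both overlapped H3K4me1 regions. The highest-scoring peak of pre-B alone was on chromosome 3 at 143813798 to 143814523, with a score of 806. That of follicular B alone was on chromosome 2 at 98502032 to 98503431, with a score of 865 and rank 298. It overlapped no H3K4me1 region of pro-B cells, and the next follicular peak of this kind had a score of 190 and rank 1478. No filter for regions prone to artifacts was applied here, so this outlier may not be a binding site. The highest-scoring peak of germinal center B alone was on chromosome 15 at 25294772 to 25295147, with a score of 112.

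The second comparison set the H3K27me3 regions of the 4 stages side by side. Pro-B cells had 28082 regions covering 43.2 Mb, pre-B cells 10570 covering 19.6 Mb, follicular B cells 9306 covering 6.89 Mb and germinal center B cells 24926 covering 29.6 Mb. The follicular regions were short, the widest being 7122 bp, against 133113 bp in pro-B, 69513 bp in pre-B and 65830 bp in germinal center B cells. After regions within 5 kb were merged, 590 domains of 20 kb or more were found in pro-B, 142 in pre-B, 42 in follicular B and 229 in germinal center B cells. The share of tags inside regions, which the file headers call the approximate IP efficiency, was 23.32% in pro-B, 5.53% in pre-B, 1.04% in follicular B and 5.61% in germinal center B cells. The libraries thus differed in depth and in the share of tags inside regions as well as in stage. A difference in the mark itself would also change that share.

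**Figure D2:**
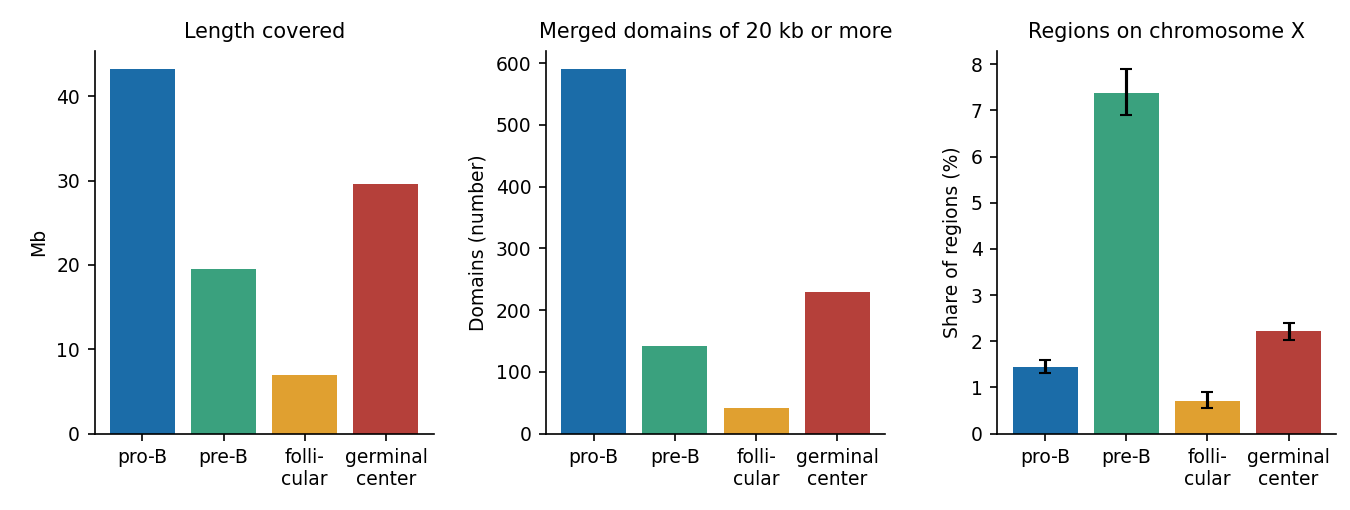
H3K27me3 regions at the 4 stages, 1 library each, as the length covered in Mb (left), the number of domains of 20 kb or more after merging within 5 kb (middle) and the share of regions on chromosome X in percent with 95% Wilson intervals (right). Covered length ran from 6.89 Mb in follicular B to 43.2 Mb in pro-B cells, and the X share of regions was highest in pre-B cells, at 7.38% by count and 3.12% by covered bases.

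Part of the covered bases was held in common. Of the bases in pre-B regions, 84.0% were also in pro-B regions, and 62.4% were in germinal center regions. Follicular bases were in pro-B regions for 67.8%, in pre-B regions for 59.1% and in germinal center regions for 58.3%. Germinal center bases were in pro-B regions for 51.2%. These overlaps were 27.2 to 71.0 times the mean of the shifts and outside their range for each of the 6 pairs. The shares depended on the lengths compared. With every list limited to its highest-scoring regions at an equal covered length, 18.3 to 29.1% of the bases were shared across the 6 pairs, 28.9% for pro-B and pre-B, which was 61.4 to 96.1 times the mean of the shifts. The 2897 merged regions touched by regions of all 4 stages had a median width of 5467 bp. They made up 20.5 of the 61.8 Mb covered in any stage. That is their full width, not bases shared by all 4 stages. Such bases cannot exceed the 4.01 Mb shared by follicular and germinal center regions. Regions of 1 stage alone were narrow, with a median width of 500 bp in each of the 4 lists. That is the smallest width of a region, and joining regions of several stages widens a merged region. The contrast in width is therefore partly built in.

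The widest merged domain in pro-B cells spanned 270 kb on chromosome 15, at 102711111 to 102981558. H3K27me3 regions covered 85.2% of it in pro-B, 61.1% in pre-B, 15.5% in follicular B and 56.8% in germinal center B cells, and no stage had a YY1 peak in it. The next widest pro-B domains lay on chromosome 11 at 96004675 to 96182375, chromosome 19 at 44713387 to 44884181, chromosome 2 at 74478274 to 74604238 and chromosome 6 at 52156991 to 52281806. Each held regions at all 4 stages. Pro-B coverage of these was 71.3 to 94.8%, and follicular coverage was 7.40 to 29.1%. The domain on chromosome 6 held 2 pro-B, 4 pre-B and 1 follicular YY1 peak, and that on chromosome 11 held 2 pro-B and 1 pre-B peak.

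**Figure D3:**
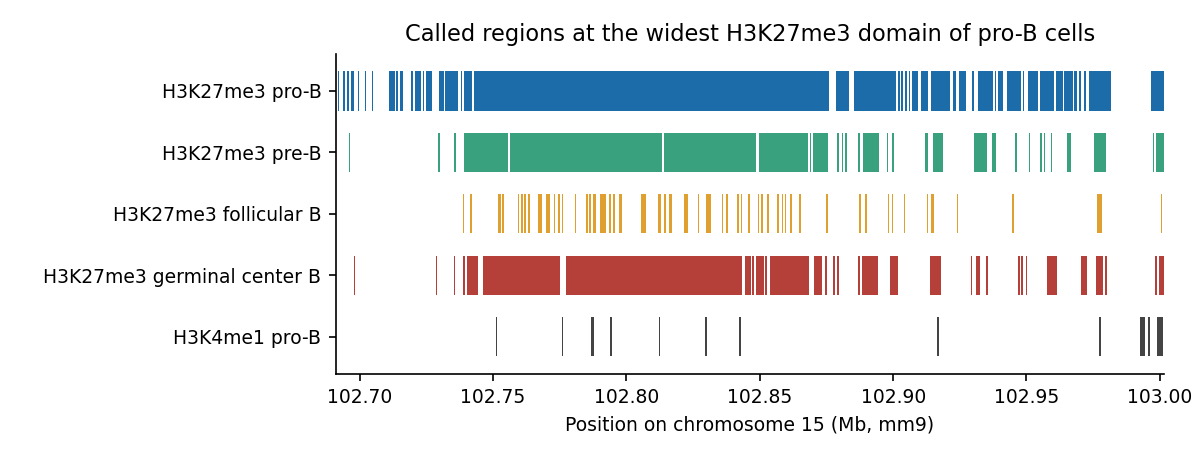
Map of the called regions along chromosome 15 (horizontal axis, position in Mb, mm9) at the widest H3K27me3 domain of pro-B cells, with 1 row of bars for each H3K27me3 library and for H3K4me1 in pro-B cells. The pro-B regions cover 85.2% of the domain, and the 52 follicular regions in it cover 15.5%.

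Some wide domains were present at 1 stage with no region at another. The widest pro-B domain with no germinal center region was on chromosome 4 at 44696162 to 44742980. H3K27me3 covered 62.1% of it in pro-B and 12.1% in pre-B cells, and neither mature stage had a region there. H3K4me1 covered 48.1% of this domain in pro-B cells, and the pro-B, pre-B and follicular lists each had 2 YY1 peaks in it. In the other direction, the widest germinal center domain absent from pro-B cells was on chromosome 9 at 33366901 to 33414629, with 36.4% coverage in germinal center B cells and no region at the other 3 stages. A germinal center domain on chromosome 2, at 101438290 to 101474498, had 24.3% H3K27me3 coverage in germinal center B and 2.76% in follicular B cells, and none in pro-B or pre-B cells. H3K4me1 covered 58.2% of that interval in pro-B cells. It held 2 YY1 peaks in each of the pro-B and pre-B lists and none in the follicular or germinal center list. Of the 976 merged germinal center domains of 10 kb or more, 187 had no pro-B region. Of the 1734 pro-B domains of that width, 259 had no germinal center region. Over merged domains of all widths, 63.5% of the germinal center and 64.4% of the pro-B domains had no region at the other stage.

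The third comparison asked whether YY1 peaks lay in Polycomb-marked chromatin, since YY1 has been proposed to recruit Polycomb group proteins. Few did. The centre of the peak was inside an H3K27me3 region of the same stage for 193 of 8662 pro-B peaks, 2.23% (1.94 to 2.56%), and for 49 of 7503 pre-B peaks, 0.653% (0.494 to 0.862%). It was inside for 5 of 5055 follicular peaks, 0.0989% (0.0423 to 0.231%), and for 10 of 2047 germinal center peaks, 0.489% (0.266 to 0.897%). Relative to the mean of the circular shifts, the share was 0.340-fold in follicular B and 0.386-fold in germinal center B cells, both below the 95% range of the shifts. With equal covered lengths of H3K27me3 the germinal center value was 0.169-fold and within the range, at 0.0489% of peaks against 0.288% in the shifts. Over all regions, the share was 1.199-fold in pro-B and 0.785-fold in pre-B cells, both within the range. The pro-B value turned with the setting. It was above the range with equal covered lengths (1.61-fold), overlap of 1 bp (1.28-fold) and random placement (1.201-fold). It was below the range with the higher-scoring part of each list (0.610-fold) and with as many high-scoring peaks as germinal center B cells had (0.234-fold). The pre-B value rose to 1.04-fold with overlap of 1 bp and 1.203-fold with equal covered lengths, within the range both times, and fell below it, to 0.290-fold, with as many high-scoring peaks as germinal center B cells had. When each peak was moved by 10 to 100 kb in place of the circular shift, the shares were 0.721-, 0.444-, 0.198- and 0.188-fold in pro-B, pre-B, follicular B and germinal center B cells, all below the range of the moves. This holds for the peak centre. At 1.5 kb beside it the share was higher at each stage, at 2.85%, 1.29%, 0.208% and 2.08% in the same order. At 5 kb it was 1.95%, 0.860%, 0.297% and 2.44%, and the means of the moves were 3.09%, 1.47%, 0.499% and 2.61%.

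**Figure D4:**
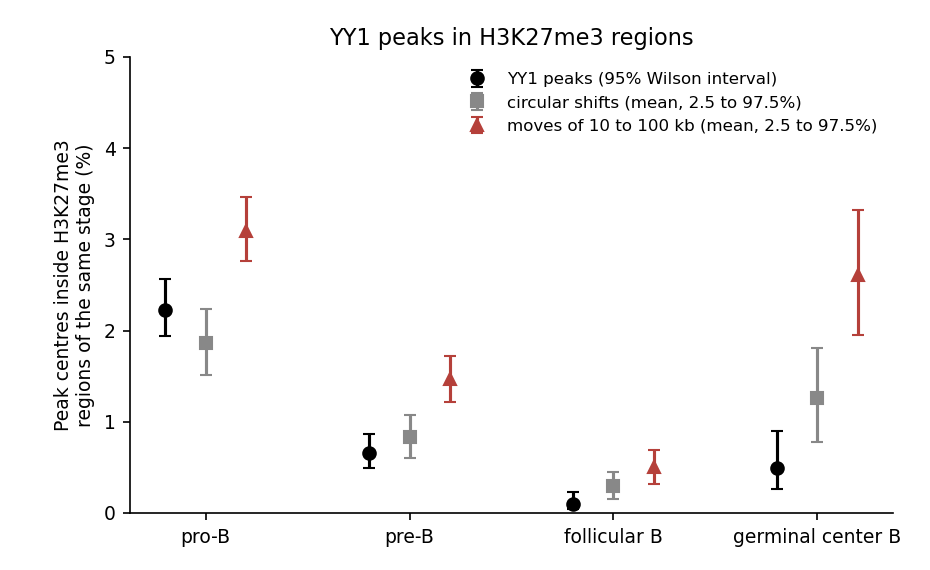
Share of YY1 peaks whose centre is inside an H3K27me3 region of the same stage, in percent (vertical axis), for the 4 stages (circles, 95% Wilson interval), with the mean and the central 95% range of 1000 circular shifts (squares) and of 1000 sets of moves by 10 to 100 kb (triangles). The share was below the moves of 10 to 100 kb at each stage, and below the circular shifts in follicular B and germinal center B cells.

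Within the pro-B list the share differed between classes of peak. Of the 1679 pro-B peaks in regions shared by all 4 stages, 0.536% (0.282 to 1.02%) were centred in H3K27me3, 0.283-fold of the shifts. Of the 3242 peaks of pro-B alone, 4.04% (3.42 to 4.77%) were. This was 2.18-fold of the shifts and 1.39-fold of the moves by 10 to 100 kb, above both ranges. These peaks had a median score of 69.4, near the lowest of that list, 55.97. The pro-B H3K27me3 regions had a median score of 7 against a lowest of 6. Peaks of pre-B alone were centred in pre-B H3K27me3 in 0.939% (0.587 to 1.499%) of cases, 1.12-fold of the shifts and within their range.

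The fourth comparison set YY1 against H3K4me1 in pro-B cells. Of the pro-B YY1 peaks, 75.3% (74.4 to 76.2%) overlapped an H3K4me1 region, 11.7-fold of the shifts and 4.57-fold of the moves by 10 to 100 kb, and 87.99% (87.3 to 88.7%) had a region within 1 kb. The mark lay beside the peak more often than at its centre. It was present at the centre of 42.9% (41.9 to 43.9%) of pro-B peaks and at 61.0% of positions 1 kb away, and 32.04% (31.1 to 33.03%) of peaks had their centre outside the mark with regions within 2 kb on both sides, against 0.892% in the shifts and 2.42% in the moves by 10 to 100 kb. Peaks in regions shared by all 4 stages had the mark at their centre in 25.5% (23.5 to 27.6%) of cases, and peaks of pro-B alone in 55.1% (53.4 to 56.8%). By any overlap the order was the other way round, 83.6% (81.8 to 85.3%) against 68.5% (66.9 to 70.1%), with median peak widths of 1117 and 581 bp, so the order depends on the rule. Peaks of later stages also overlapped pro-B H3K4me1 regions, in 70.4% (69.3 to 71.4%) of cases for pre-B, 69.2% (67.9 to 70.5%) for follicular B and 52.0% (49.8 to 54.1%) for germinal center B cells.

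**Figure D5:**
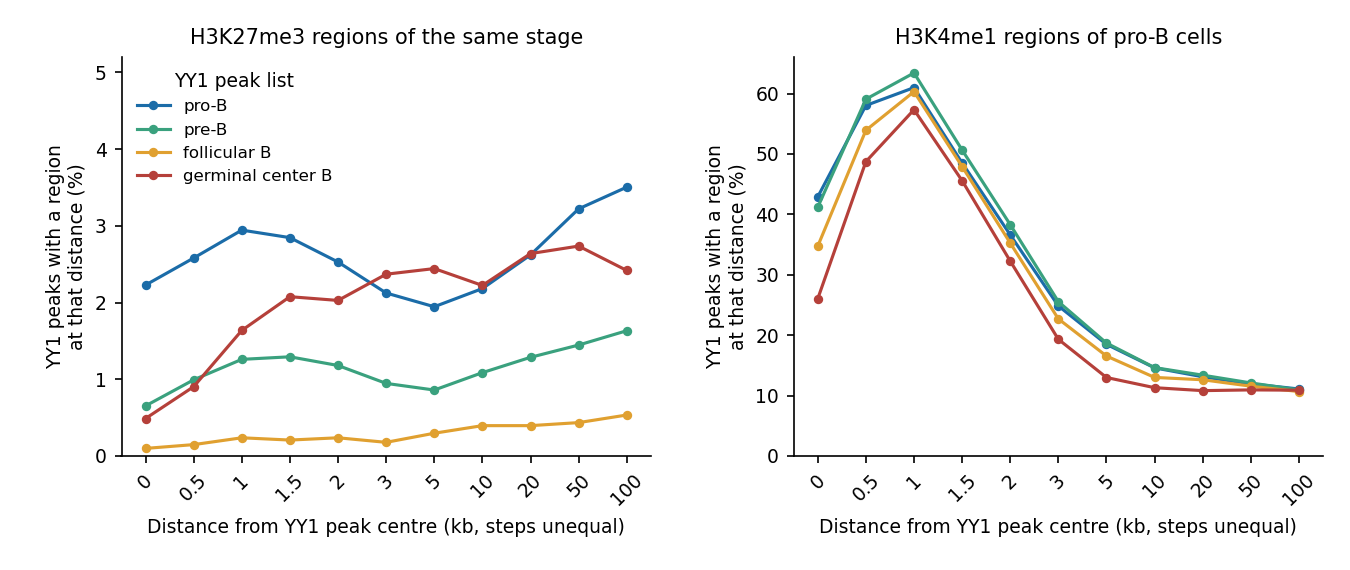
Share of YY1 peaks, in percent (vertical axis), with an H3K27me3 region of the same stage (left) or an H3K4me1 region of pro-B cells (right) at the given distance in kb from the peak centre (horizontal axis, unequal steps), averaged over both sides, with 1 line for each YY1 list. In pro-B cells H3K4me1 rose from 42.9% at the centre to 61.0% at 1 kb, and the germinal center list rose from 26.0% to 57.3%.

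The last comparison set the histone marks of pro-B cells against each other. H3K4me1 had 52797 regions covering 108 Mb. They held 16.2% of the bases in H3K27me3 regions, 3.45-fold of the mean of the shifts and 2.26-fold of that of moves by 10 to 100 kb, above both ranges. Of the 28082 H3K27me3 regions, 5304 overlapped an H3K4me1 region, 18.9% (18.4 to 19.3%), and 10.5% (10.2 to 10.8%) of the H3K4me1 regions overlapped H3K27me3. The widest merged H3K4me1 domain, on chromosome 11 at 22654943 to 22780388, held no H3K27me3 region at any stage and had 1 pro-B and 2 pre-B YY1 peaks. The next, on chromosome 11 at 118004671 to 118128620, likewise held no H3K27me3 region and had 2 pro-B, 4 pre-B and 2 follicular YY1 peaks.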

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

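The tests of covered length, clustering and list length in this part were chosen after the result had been seen, except that covered length was among the alternatives fixed before the data were examined.

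YY1 peaks lay in H3K27me3 of the same stage 1.199-fold as often as the circular shifts in pro-B cells, against 0.340-fold in follicular B and 0.386-fold in germinal center B cells, opposite sides of the shifts. The difference between stages was not tested, since each stage had 1 library, and the pro-B value was within the 95% range of its shifts. With equal covered lengths the pro-B value was 1.61-fold, at 0.473% of peaks against 0.294% in the shifts. The share in the shifts changes with covered length too, so this cannot decide on a larger H3K27me3 coverage in pro-B cells. It shows that the value stayed above 1 within the higher-scoring regions when all YY1 peaks were kept. With the higher-scoring part of both lists the pro-B value was 0.610-fold, below the range. Clustering of both kinds of region along chromosomes may account for the opposite sides, since both stages were below the moves of 10 to 100 kb. The values were 0.721-fold in pro-B (0.627 to 0.829) and 0.188-fold in germinal center B cells (0.102 to 0.344). These are Wilson intervals over peaks divided by the mean of the moves, and they cover counting error only. The germinal center value rests on 10 peaks, and the moves were not made with lists of equal length. The intervals lie apart, so for these lists clustering is argued against only as the source of the remaining difference in size. The longer pro-B list, which reaches weaker peaks, remains a candidate explanation, because its highest-scoring peaks at the germinal center length gave 0.234-fold. Whether the weaker pro-B peaks in H3K27me3 reflect binding particular to that stage was not tested.

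Chromosome Y was outside the overlap comparisons and held 4 YY1 peaks in pro-B cells, above the limit of 3 used to flag results. Passing that limit is no test, since peaks are not independent counts and the lists have different lowest scores. The pre-B list had 3, the germinal center list 2 and the follicular list 0.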

How the results depend on the processing

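The common lowest score, moves of 10 to 100 kb, equal YY1 list length against H3K27me3, chromosomes 1 to 19 alone and the centre rule for H3K4me1 were chosen after the data had been seen, and the other alternatives before. Some alternatives left a stage's own value unchanged by construction, and these are counted as kept. Thus the follicular list set the equal covered length and had no peak on chromosome Y. The germinal center list set the equal YY1 list length and the pre-B list the common lowest score. Of 117 values under alternatives fixed beforehand, 97 kept direction and side of the threshold or stayed within 1.5 times. Of 38 under added ones, 31 did. All alternatives of the YY1 overlaps between stages, the H3K27me3 overlaps between stages, the score difference of shared peaks, YY1 in H3K4me1 and the overlap of the histone marks kept both, though sizes moved. The YY1 overlaps ran from 40.9-fold (moves of 10 to 100 kb) to 854-fold (200 bp around the centre), and the H3K27me3 overlaps from 16.5-fold (merged within 5 kb) to 96.1-fold (equal covered length, with 18.3 to 29.1% of bases shared against 51.2 to 84.0%). YY1 in H3K27me3 did so in follicular B cells, where equal covered length was no change, and not at the other stages. The pro-B value of 1.199-fold reversed with the higher-scoring part of each list (0.610), moves of 10 to 100 kb (0.721) and equal YY1 list length (0.234), and passed the range of the comparison with random placement (1.201), overlap of 1 bp (1.28) and equal covered length (1.61). The pre-B value of 0.785-fold turned above 1 with overlap of 1 bp (1.04) and equal covered length (1.203), within the range both times, and fell below the range with moves of 10 to 100 kb (0.444) and equal YY1 list length (0.290). The germinal center value with equal covered length was lower (0.169) and yet no longer passed, at 0.0489% of peaks against 0.288% in the shifts. Losing the call there does not mean a value nearer to the shifts. The causes of these changes were not tested.

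By construction, counts fell under stricter settings. The common lowest score left 5452 pro-B, 3053 follicular and 1254 germinal center YY1 peaks, and the higher-scoring part of each list left 999 regions shared by all 4 stages. For H3K27me3 it left 14041, 5285, 4653 and 12463 regions in pro-B, pre-B, follicular B and germinal center B cells, covering 12.7 Mb in pre-B, 4.07 Mb in follicular B and 18.7 Mb in germinal center B cells. Merging within 5 kb gave 14930 pro-B and 15443 germinal center regions, and covered lengths of 66.8 Mb in pro-B, 11.8 Mb in follicular B and 47.0 Mb in germinal center B cells. Merging thus put the germinal center number above the pro-B number.

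Promoter and gene-list alternatives were not run, as no annotation of mm9 was used here. No paired analysis was possible because each group had 1 library and the labels carry no replicate numbers. The H3K27me3 libraries differed in depth and in the share of tags inside regions. A region missing from a list, above all the follicular one, was not detectable there and is not shown to be absent.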

Other observations

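In this part, the tests of the input on chromosome X and of the spread along X were written before their results were seen, and those of depth, ChIP enrichment, loss of domains, gained H3K27me3 and chromosome Y after.

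Pro-B H3K27me3 regions that also carried H3K4me1 were found again at later stages more often than those without it. Of the regions from 1000 to under 5000 bp with H3K4me1, 75.4% (73.7 to 77.1%) overlapped a pre-B, 44.3% (42.4 to 46.2%) a follicular and 78.4% (76.8 to 79.9%) a germinal center H3K27me3 region. The shares without H3K4me1 were 36.0% (34.6 to 37.3%), 14.5% (13.5 to 15.5%) and 32.6% (31.3 to 33.9%). The regions with H3K4me1 were wider within this class, with a median of 2640 against 1658 bp. At 5000 bp or more the shares in pre-B were 99.7 and 98.01%, and under 1000 bp they were 19.9 and 4.05%.

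The 232 YY1 peaks of germinal center B cells alone differed from the rest of that list. They overlapped pro-B H3K4me1 regions in 8.62% (5.65 to 12.9%) of cases, 1.63-fold of the circular shifts and above their range, and 1.38-fold of the moves by 10 to 100 kb and within theirs, against 56.8% (54.4 to 59.1%) for germinal center peaks shared by all 4 stages. Their median width was 424 bp, and their median score was 54.6, near the lowest score of that list, 50. Germinal center peaks in 2 or 3 stages had a median width of 429 bp and overlapped in 68.1% (59.2 to 75.8%) of cases. Weak or false peaks would also overlap rarely, which was not tested. Peaks shared by all 4 stages are pro-B peaks by definition, and the mark was mapped in pro-B cells only. Peaks of pre-B alone overlapped pro-B H3K4me1 regions in 72.7% (70.6 to 74.7%) of cases and peaks of follicular B alone in 58.2% (54.8 to 61.5%).

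Chromosome X held 7.38% of the pre-B H3K27me3 regions (780 of 10570), against 1.44% in pro-B, 0.698% in follicular B and 2.21% in germinal center B cells. By covered bases the shares were 3.12%, against 1.13%, 0.509% and 1.42%, and 69.6% of the pre-B regions on X had the smallest width, 500 bp. Deeper sequencing is argued against, since the follicular library had the most tags and an X share of 0.698%. An input poor in X remains open. Over regions of 500 bp, the pre-B input tags on X were 0.943 times those on autosomes, against 0.873 to 0.892 in the other libraries, but this decides nothing, since every region had to pass a 4-fold ratio over the input. That fault in the test was seen only after its result, which by the rule set beforehand would have argued against such an input. A rise spread along the whole chromosome, as on an inactive X, remains open. Pre-B regions found in no other stage lay in 73.8% of the 1 Mb windows of X, short of the 80% set beforehand, while 21.9% of the pre-B X regions were in another stage. The share of females in each pool is not given in the sources used here, so the sex of the mice and the stage cannot be told apart.

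The follicular H3K27me3 regions were short, covering 6.89 Mb. Lower depth is argued against, as that library had 20.2 M tags, the most of the 4. Complete loss of the wide domains is argued against, since 88.5% of the 590 pro-B domains of 20 kb or more held a follicular region, 9.68-fold of the shifts. Lower enrichment of the ChIP is consistent with that value, with 10.5% of the length of those domains covered in follicular B cells against 35.0% in pre-B and 31.9% in germinal center B cells. A lower level of the mark in follicular B cells would look alike and was not tested.

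A hypothesis was that germinal center B cells gain H3K27me3 at sites of earlier YY1 binding. Of the 16435 germinal center regions with no pro-B H3K27me3, 1.19% (1.03 to 1.36%) overlapped a pro-B YY1 peak. This was 2.18-fold of the circular shifts and 1.07-fold of the moves by 10 to 100 kb, within the range of the latter. An excess at the sites themselves over their neighbourhood was not detectable in these lists.

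Another hypothesis started from chromosome Y, where the follicular YY1 list had no peak while 2 regions were in the pro-B, pre-B and germinal center lists. A short follicular list is argued against only on average, since it missed 1.76% of the merged regions that the other 3 lists held on the other chromosomes. The 2 regions had germinal center scores of 73.1 and 58.9, near the lowest of that list, and pro-B scores of 597 and 286. No rate was made for regions of like score, so a short list is not excluded for them. A pool with fewer Y-bearing cells may be behind the missing Y peaks, and it would also raise the share of peaks on X. With lists of at most 5055 peaks, that share was 3.07% (2.63 to 3.58%) in follicular B against 2.29% (1.92 to 2.75%) in pro-B, 2.47% (2.08 to 2.94%) in pre-B and 2.25% (1.69 to 2.98%) in germinal center B cells. The intervals overlap, so the explanation stays open.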
